A study of Mus musculus with 2 samples.

How the data were processed

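Small RNA was sequenced from the forebrain of C57BL/6-background (B6NCrl) mouse embryos at embryonic day 14.5, in 2 libraries that the labels number as biological replicates 1 and 2. The labels describe each library as a single forebrain, collected on different days, and give the insert size range as under 30. They also give the sex as pooled, which is at odds with a single embryo, and the same donor identifier for both libraries. This was left unresolved, so the spread between the libraries may be partly technical. No second tissue, age or treatment is named, so the libraries form 1 group and no test between conditions was possible.

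The values used were whole-number read counts per annotated miRNA gene, as deposited by the authors, 1 table per library. Per the README deposited with each sample, the counts were derived from 1 alignment file per library on mouse genome build mm10 with GENCODE annotation M4. The aligner, the counter and their settings are not given in the sources used here. Each deposited table has 3 columns of counts (reads on either strand, on the strand of the gene, and on the opposite strand) and 4 totals for unmapped, multi-mapping, unannotated and ambiguous reads. In both tables each column and its totals summed to the same number of reads. Only reads that mapped to 1 place entered a gene count, and a read that matched several places was counted in the multi-mapping total. Reads that fit identical hairpins at several loci are therefore left out of the gene counts. The 4 totals name no gene and were kept out of library sizes and tests. Unmapped reads made up 16.8% ± 0.325 of the reads (SD, n = 2), multi-mapping reads 42.7% ± 0.822, uniquely mapped reads with no miRNA gene on their own strand 2.21% ± 0.189, and ambiguous reads 0%.

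Counts on the strand of the gene were used for all main results and were scaled to CPM, the count per 1000000 counts over all miRNA genes of the library. One count was worth 0.141 CPM in replicate 1 and 0.126 CPM in replicate 2, and a floor of 3 counts was 0.424 and 0.378 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers and PCR copies are not independent molecules. Levels are log2(CPM + 1), averaged over the libraries. Errors are standard deviations over 2 libraries, which give a coarse estimate of spread.

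Gene names, positions and hairpin sequences came from GENCODE M21, which is on the same assembly. Of the 1973 gene IDs, 1894 matched by ID, and the other 79 kept their IDs and had at most 2 counts each in either library. A hairpin was said to share sequence when 20 nt or more of it occurred, on either strand, in another annotated miRNA gene at a different position, which was the case for 929 hairpins. Host genes are non-miRNA genes on the same strand that contain the hairpin. Gene counts and positions belong to the hairpin locus, and the 5′ and 3′ arms were not separated.

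The following were chosen before the data were examined: the 21 miRNA lists, the tests, and the rule for named genes. That rule takes the 20 genes with the highest mean CPM, up to 3 of the highest members of every list, and the 5 genes with the largest ratio between the libraries in each direction among those at a mean of 100 CPM or more that passed the test. Any other gene named was chosen after its values were seen. The lists cover neuron-associated and neural progenitor miRNAs, the miR-17~92, let-7, miR-99 with miR-100 and miR-125, miR-181 and miR-30 families, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of erythroid, immune, endothelial, smooth muscle or stromal, striated muscle, liver, epithelial, choroid plexus or ciliated, pluripotent, Hox-cluster, sensory, and pancreas or gut origin.

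A gene was called detected at 10 or more counts in both libraries. The libraries were compared with Pearson and Spearman correlations across genes, and per gene with a two-sided Fisher's exact test of the gene against the remaining miRNA counts, with Benjamini-Hochberg adjustment over all genes, a threshold of 0.05 and at least a 2-fold difference. This test compares these libraries and knows counting error only. The median log2 ratio of each list was set against 10000 random lists of the same size matched on level in 10 bins, with adjustment over the 19 lists of at least 2 measured genes. The levels of the 2 neural lists and of 10 lists of other tissues were compared with a two-sided permutation test of the difference of medians (100000 permutations over genes). Similarity of levels within genomic clusters, defined as genes on one strand with gaps of up to 10 kb and 10 or more counts in either library, was tested one-sided by permuting levels over the same genes 10000 times. Genes are not independent replicates, and members of 1 primary transcript even less so, so p-values across genes describe these libraries and are too small as evidence about other embryos.

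Alternatives covered the count minimum, the pseudocount, filters on low counts, scaling by TMM or by median-of-ratios size factors, counts on either strand, unique hairpins alone, the cluster gap and each library alone. Scaling factors and the biological coefficient of variation were computed with edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, and the rest with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The comparison of libraries was tested on simulated counts for all 1973 genes, 200 of them changed. It called 2% of genes changed 1.5-fold, 90% of those changed 3-fold, 94% at 4-fold, 96% at 8-fold and 0.0564% of unchanged genes. The 2% at 1.5-fold follows from the 2-fold minimum. Of the 1973 genes, 1236 had no count in either library, and a gene with no count cannot be called. The 90% to 96% therefore do not extend to genes without counts. They were not measured separately for genes with few counts, so they should not be applied to those genes. Genes without counts lower the 0.0564%. The real libraries differed by far more than sampling noise (chi-square of 91022 on 444 degrees of freedom). The 0.0564% is therefore no error rate for the real comparison. No column of the tables belonged to another sample. The signal tracks named in the README were not used here.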

Results

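The miRNA content of the embryonic mouse forebrain at day 14.5, a stage at which the cortex is producing neurons, was measured by small RNA sequencing in 2 biological replicates of the B6NCrl strain. The libraries held 18598385 reads in replicate 1 and 20638071 reads in replicate 2. Reads assigned to the correct strand of a miRNA gene numbered 7080317 and 7946585, or 38.3% ± 0.308 of all reads (SD, n = 2). Of the uniquely mapped reads, 94.5% ± 0.399 fell in miRNA genes on the strand of the gene. A further 42.7% ± 0.822 of the reads matched several places and were assigned to no gene. All shares given for genes and lists are therefore shares of uniquely assigned counts.

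**Figure D1:**
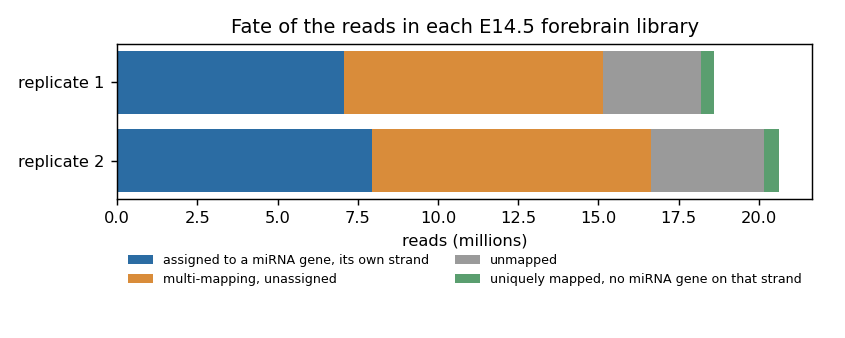
Stacked bars show the number of reads (in units of 1000000) in each of the 2 E14.5 forebrain libraries, divided by fate into assigned to a miRNA gene on its own strand, multi-mapping, unmapped and uniquely mapped with no miRNA gene on that strand. The 2 libraries divided alike, with 43.3% multi-mapping reads in replicate 1 and 42.2% in replicate 2.

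A single gene, Mir99a, held 30.1% ± 2.38 of the miRNA counts (SD, n = 2), at 301081 ± 23837 CPM. Next came the let-7 genes Mirlet7g at 58526 ± 5941 CPM and Mirlet7i at 49620 ± 5832 CPM, members of a family that accumulates as embryonic tissues differentiate. Mir335, which lies in an intron of the imprinted gene Mest, stood at 37129 ± 5161 CPM, Mir100 at 34407 ± 4069 CPM, and Mir17, of the proliferation-linked miR-17~92 cluster, at 31722 ± 5021 CPM. Mir130a followed with 29797 ± 3847 CPM, Mir99b with 23511 ± 103 CPM, Mir487b of the imprinted Dlk1-Dio3 region with 23191 ± 3648 CPM, and Mir30e with 23141 ± 3060 CPM. These 10 genes held 61.2% ± 1.47 of the counts, 60.2% in replicate 1 and 62.3% in replicate 2.

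The other genes among the 20 most abundant were the endothelial Mir126a (22234 ± 185 CPM), Mir181c, Mir149, Mir26b, Mir93, Mir20a, Mir30a, Mir322, Mir181a-1 and Mir130b (8128 ± 1512 CPM). Together the 20 held 73.8% ± 1.26 of the counts, and 53 genes held 90% of the mean CPM. On mm10, Mir99a (ENSMUSG00000065530.1) lies at chr16:77598936-77599000 on the plus strand, in an intron of the non-coding gene Mir99ahg. Mirlet7g (ENSMUSG00000065440.1) lies at chr9:106178840-106178927 in an intron of Wdr82, and Mirlet7i (ENSMUSG00000065406.2) at chr10:122985640-122985724 in an exon of D630033A02Rik. Mir335 lies at chr6:30741299-30741396, Mir17 at chr14:115043671-115043754 in an exon of Mir17hg, and Mir126a at chr2:26591357-26591429 in an exon of Egfl7. Of 1973 annotated genes, 399 (20.2%) were detected at 10 or more counts in both libraries, 84 of them at 1000 CPM or more in both, and 1236 had no count in either. A gene with no count and a unique hairpin could still hold up to 0.424 CPM in replicate 1 and 0.378 CPM in replicate 2. For hairpins that share sequence a count of 0 sets no such limit, since reads that match several loci were not counted. With a minimum of 1 count, 634 genes were detected in both.

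Among the fixed families, the miR-99, miR-100 and miR-125 group led with 36.9% ± 2.74 of the counts (SD, n = 2), and 81.6% of that was Mir99a. The let-7 family with miR-98 held 13.2% ± 0.177, with all 10 members analysed detected, and Mirlet7d stood at 7371 ± 672 CPM. All 15 genes of the miR-17~92 cluster and its paralogues were detected, with 7.05% ± 0.963 of the counts, led by Mir17, Mir93 (12296 ± 1797 CPM) and Mir20a (11310 ± 1834 CPM). The miR-30 family held 3.93% ± 0.470, and the miR-181 family 3.38% ± 0.0428, led by Mir181c at 15204 ± 816 CPM. Within the imprinted Dlk1-Dio3 region, whose miRNAs are expressed from the maternal chromosome, 45 of the 51 genes analysed were detected, with 5.80% ± 0.374 of the counts. Opposite-strand counts at the positions of Mir409, Mir376a, Mir380 and Mir299a in this region are not part of that sum. Mir487b alone made up 40.0% of that sum, ahead of Mir411 (5501 ± 268 CPM) and Mir369 (4339 ± 219 CPM). Members of the repeat-rich cluster in the introns of Sfmbt2 held 0.337% ± 0.0329, led by Mir467d at 1143 ± 167 CPM, and 10 of 67 were detected. Hairpins that share 20 nt or more with another carried part of these sums. Without them the share was 2.90% for Dlk1-Dio3, 2.17% for miR-181 and 0% for Sfmbt2, whose 67 members include 65 that share sequence.

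The neuron-associated list was detected in 17 of 18 genes and held 1.54% ± 0.0454 of the counts (SD, n = 2). Its highest members were Mir137 (7614 ± 481 CPM), Mir7b (2120 ± 167 CPM) and Mir153 (1649 ± 174 CPM), which all have a hairpin sequence of their own. Of the neural progenitor list, with 0.370% ± 0.0492 of the counts, Mir92b stood at 3097 ± 439 CPM, Mir9-3 at 595 ± 55.5 CPM and Mir9-2 at 5.00 ± 1.47 CPM. The 3 loci of miR-124, the best-known miRNA of neurons, were named after their values were seen. They were close to the floor, with 18 and 15 counts at Mir124a-1, 10 and 17 at Mir124a-2, and 3 and 4 at Mir124a-3 in replicates 1 and 2. Of the 18 neuron-associated genes, 13 share 20 nt or more with another hairpin, among them the 3 Mir124a loci, so their counts leave out reads that match more than 1 locus. The levels of miR-124 and miR-9 in this tissue cannot be read from these gene counts.

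Markers of other cell types were present at widely different levels. The endothelial Mir126a held 2.22% ± 0.0185 of the counts (SD, n = 2), more than any other list of cell type markers. The choroid plexus and ciliated cell list held 0.737% ± 0.0996, with Mir449a of multiciliated cells, in an intron of Cdc20b, at 4268 ± 784 CPM, Mir204, in an intron of Trpm3, at 1935 ± 67.3 CPM and Mir34c at 1126 ± 137 CPM. Smooth muscle and stromal markers held 0.390% ± 0.0297, of which 92.6% was Mir143 (3612 ± 300 CPM), with Mir214 at 135 ± 0.364 CPM and Mir145a at 78.4 ± 2.72 CPM. Epithelial miRNAs held 0.188% ± 0.0375, led by Mir203 (1294 ± 106 CPM), Mir429 (352 ± 190 CPM) and Mir200b (118 ± 42.8 CPM).

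Erythroid miRNAs held 0.0474% ± 0.00972 of the counts (SD, n = 2), nearly all of it Mir451a at 457 ± 86.3 CPM. The immune list held 0.0189% ± 0.000383, with Mir223 of myeloid cells at 81.0 ± 7.13 CPM, Mir155 at 69.0 ± 5.53 CPM and Mir150 at 38.6 ± 2.22 CPM. Counts on either strand gave an immune share of 0.0322%. They include Mir142b, a gene model antisense to the blood-cell gene Mir142, which had counts on the opposite strand only. Hox-cluster miRNAs, which mark posterior body regions, held 0.0599% ± 0.00988, with Mir10a at 320 ± 69.2 CPM, Mir10b at 236 ± 26.4 CPM and Mir196b at 27.7 ± 4.23 CPM. Pancreas and gut miRNAs held 0.0421% ± 0.00218, led by Mir375 at 219 ± 32.9 CPM. The pluripotency clusters held 0.0355% ± 0.00479, led by Mir302a at 165 ± 28.1 CPM, and 0.0135% without hairpins that share sequence. The sensory cluster of Mir183, Mir96 and Mir182 held 0.0309% ± 0.00657, led by Mir182 at 164 ± 23.4 CPM. Lowest were striated muscle miRNAs with 0.00251% ± 0.000590, led by Mir206 at 16.4 ± 3.97 CPM, and the hepatocyte miRNA Mir122 at 10.3 ± 0.0829 CPM. Of the 10 striated muscle genes, 5 share 20 nt or more with another hairpin, so their counts leave out reads that match more than 1 locus.

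**Figure D2:**
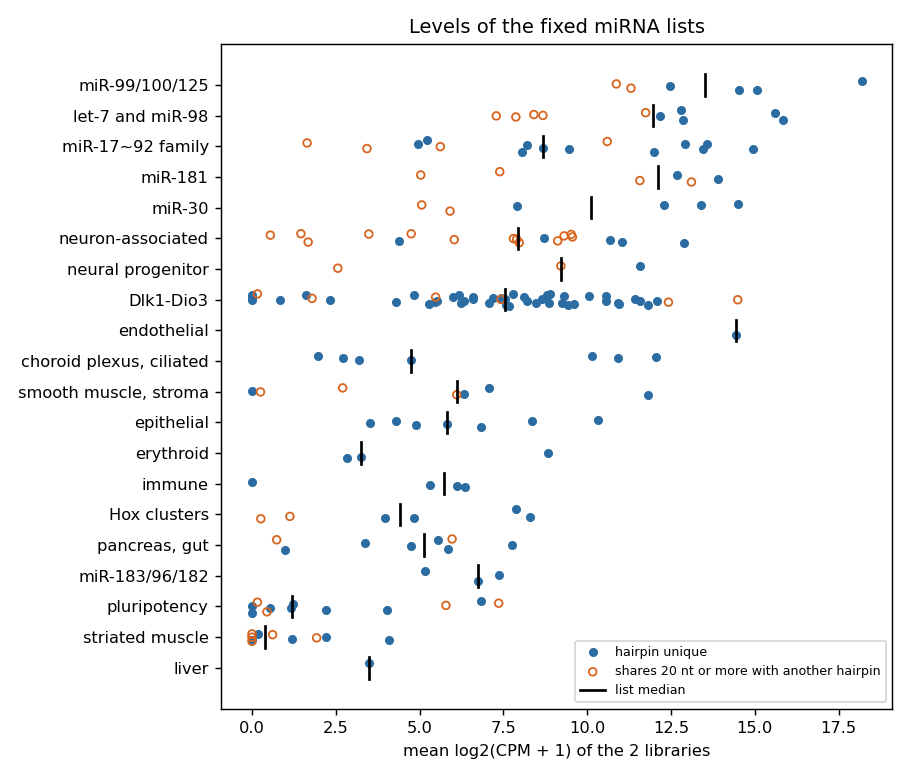
Each point is 1 miRNA gene at its mean log2(CPM + 1) over the 2 libraries (horizontal axis), grouped by 20 of the fixed lists (vertical axis, with points spread for visibility), as a filled point for a unique hairpin, an open point for a hairpin that shares 20 nt or more with another, and a black line for the list median. Among neuron-associated genes 13 of 18 points are open, and the list median is 7.93.

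Whether neural miRNAs stood above those of other tissues was asked by comparing 21 genes of the neural lists with 59 genes of 10 lists of other tissues, which leave out the choroid plexus or ciliated and the sensory lists. The median level was 7.97 for the neural genes and 3.54 for the others on the log2(CPM + 1) scale. The difference of 4.44 passed a two-sided permutation test over genes (p = 0.00116). The neural genes thus stood higher although 15 of them share sequence with another hairpin. In uniquely assigned counts, single genes of other tissues still exceeded them, and Mir126a stood above every member of the neural lists. For the 15 neural genes that share sequence this ranks counts only, since their reads that match several loci are missing.

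miRNA genes that lie close together on a chromosome had more similar levels than genes drawn at random. In 47 clusters with 164 genes, the mean standard deviation within a cluster was 2.65 log2 units, against 3.11 after permutation (one-sided permutation p = 0.0223). The largest cluster held 31 genes of the Dlk1-Dio3 region at chr12:109709060-109747960, from 1.62 to 14.49 on the log2(CPM + 1) scale. At the Mir17hg locus, chr14:115043671-115044506, 6 genes ranged from 3.43 to 14.94, and Mir99a stood 9.79 log2 units above its neighbour Mirlet7c-1, which shares sequence with another hairpin. The call was lost without replicate 1 (p = 0.0695 in the same permutation test) and held without replicate 2 (p = 0.0411). With no filter on low counts, 104 clusters with 414 genes had a mean of 1.66 against 3.36 after permutation (permutation p = 1e-04, the smallest that 10000 permutations can give). This setting adds genes below the count minimum, and neighbours at or near 0 counts have similar levels by default. Among them are genes of the Sfmbt2 cluster, where 57 of 67 were not detected and 65 share sequence. The value therefore says little about similar expression.

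The replicates had similar miRNA profiles. Across 445 genes with 10 or more counts in either library, Pearson's r was 0.995 and Spearman's rho 0.989 on log2(CPM + 1), with genes not being independent replicates. Detected genes lay a median of 1.17-fold apart, 90.0% of them were within 1.5-fold and 98.5% within 2-fold. The common biological coefficient of variation from edgeR was 15.1%. The counts differed by far more than sampling noise (chi-square of 91022 on 444 degrees of freedom), so the files do not hold 1 library deposited in duplicate.

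Between the libraries, 7 genes passed Fisher's exact test (Benjamini-Hochberg adjusted) with at least a 2-fold difference, 4 of them higher in replicate 2 and 3 higher in replicate 1. One of these reached 100 CPM. It was Mir429 of the miR-200 family, which marks epithelia, at 2.23-fold higher CPM in replicate 2 (Fisher's exact test, adjusted p = 1.45e-169). The other 6 were named after their values were seen and had low counts. Mir144, an erythroid miRNA, had 26 and 145 counts in replicates 1 and 2 (4.97-fold), Mir669f of the Sfmbt2 cluster 7 and 73 (9.29-fold), and Mir7056 0 and 10, at least 2.97-fold higher against a floor of 3 counts. Higher in replicate 1 were Mir449c of multiciliated cells (61 and 28 counts, 2.45-fold), Mir6897 (36 and 18, 2.24-fold) and Mir6968 (14 and 1), the last with a ratio of 15.7 and a 95% Wilson counting interval of 2.64 to 93.5. With no minimum fold, 178 genes passed, 63 higher in replicate 2 and 115 higher in replicate 1. Scaling moved this split to 79 and 88 genes with TMM and to 90 and 80 with median-of-ratios factors, and that of the 2-fold calls to 6 and 2 and to 7 and 2. With either scaling, and with totals that leave out Mir99a, 6 of the 7 genes kept their call and Mir6897 lost it.

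Among abundant genes that passed Fisher's exact test, the largest ratios toward replicate 2 after Mir429 were those of Mir200b (1.69-fold), Mir183 (1.69-fold), Mir128-1 (1.60-fold) and Mir700 (1.45-fold). Toward replicate 1 they were Mir106a (1.60-fold), Mir20b (1.58-fold) and Mir28a (1.57-fold), followed by Mir298 (1.48-fold) and Mir15a (1.47-fold). Mir106a and Mir20b belong to a paralogue of the miR-17~92 cluster on the X chromosome.

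As lists, epithelial miRNAs were higher in replicate 2 and the miR-17~92 family was higher in replicate 1. The epithelial list had a median log2 ratio (replicate 2 over 1) of 0.90, with 6 of 7 genes higher in replicate 2 (adjusted p = 0.00380 against random lists matched on level). Its 5 miR-200 family genes had a summed ratio of 2.05. Mir203, with 68.8% of the list's counts, had a ratio of 1.12, and Mir205 one of 0.862. The miR-17~92 family had a median of -0.36, with 14 of 15 genes higher in replicate 1 (adjusted p = 0.00475). The let-7 family had a median of 0.21, with 8 of 10 genes higher in replicate 2 (adjusted p = 0.0374), although Mirlet7i was 1.18-fold higher in replicate 1. This list lacks Mirlet7e and Mirlet7f-1. Opposite-strand counts at their positions were 3394 and 3289 CPM for Mirlet7e and 90.0 and 91.2 CPM for Mirlet7f-1 in replicates 1 and 2. All 6 miR-30 genes were higher in replicate 1, with a median of -0.34 that did not pass (adjusted p = 0.138), and neither did the neuron-associated list at -0.13 (adjusted p = 0.578). The choroid plexus and ciliated cell list had a median of -0.27, with 7 of 7 genes higher in replicate 1 (5 of 7 with TMM), and did not pass either (adjusted p = 0.379). The directions of these list medians held with TMM, with median-of-ratios factors and with totals that leave out Mir99a, which moved all log2 ratios up by 0.08, 0.11 and 0.07. The collection day differed between the libraries, so it cannot be told apart from any other difference between them.

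**Figure D3:**
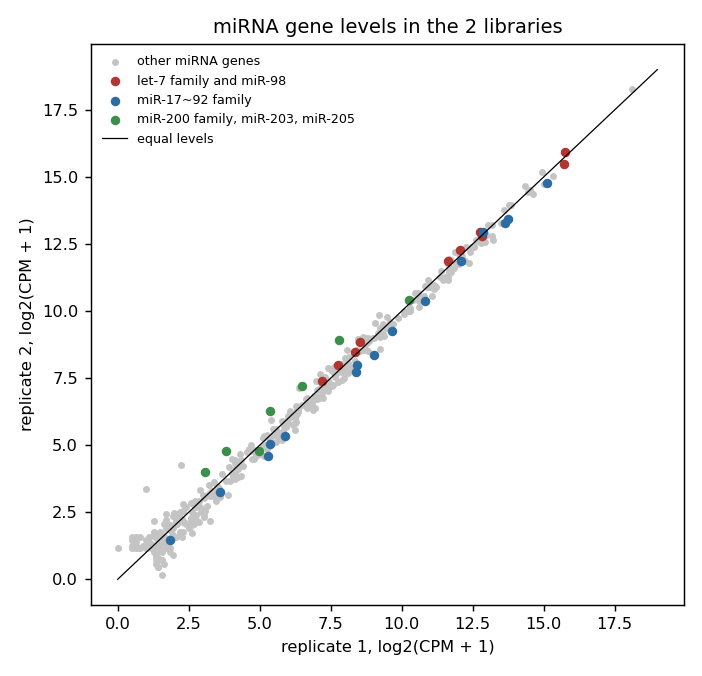
Each point is 1 of 445 miRNA genes at its log2(CPM + 1) in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the let-7, miR-17~92 and epithelial lists coloured and a line of equal levels. Points lie close to the line (Pearson's r = 0.995), with 14 of 15 miR-17~92 genes on the side of replicate 1 and 6 of 7 epithelial genes on the side of replicate 2.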

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

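The comparison of opposite-strand counts with the other-strand annotation, and the tests of the size of the unassigned pool and of low expression, were chosen after the values were seen.

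Counts on the opposite strand, which no main result uses, made up 1.40% ± 0.0337 of the counts at miRNA genes (SD, n = 2), far above the limit that a count of 0 allows. They were concentrated in 11 gene models, which held 99.6% of them in replicate 1 and 99.7% in replicate 2, and 8 of these models had no count on their own strand. At each of the 11, GENCODE M21 places on the other strand a miRNA gene that is not among the genes analysed here. In CPM over the same library totals, the opposite strand of Gm24321 held 3682 ± 98.5 (the position of Mir409), that of Gm25927 held 3341 ± 74.3 (Mirlet7e), that of Gm25252 held 2250 ± 99.3 (Mir376a) and that of Gm24083 held 1820 ± 19.0 (Mir191). Lower values were found at Gm25301 with 1271 ± 171 (Mir378a), Gm25750 with 664 ± 107 (Mir380), Mir299b with 451 ± 62.6 (Mir299a) and Mir497b with 338 ± 49.7 (Mir497). The lowest were Mir142b with 138 ± 0.781 (Mir142), Gm24111 with 90.6 ± 0.896 (Mirlet7f-1) and Gm25641 with 62.7 ± 11.6 (Mir9-1). The list sums of the report leave these counts out. Left out are those at the positions of Mirlet7e and Mirlet7f-1 for the let-7 family and of Mir142 for the immune list. The same holds for Mir9-1 and the neural progenitor list. The positions of Mir409, Mir376a, Mir380 and Mir299a lie in the Dlk1-Dio3 region, whose reported share does not include them.

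Multi-mapping reads, which name no gene, made up 42.7% ± 0.822 of the libraries (SD, n = 2), and multi-copy miRNAs such as miR-124 had few gene counts. Within 18 clusters, members that share 20 nt or more with another hairpin differed from the other members by a median of -4.12 log2 units (lower in 14 of 18 clusters, sign-flip permutation p = 0.00074), so loss of reads that match several loci is a candidate explanation. Some of these clusters hold copies of the same miRNA, such as Mirlet7a-1 and Mirlet7a-2. The 18 clusters are therefore not independent, and the p-value is too small. There were at least 1.09 multi-mapping reads per assigned read in each library, but the part of this pool that comes from miRNAs is not known, so its size decides nothing. Low expression of the multi-copy miRNAs in this tissue stays open, because the 42.7% of reads in the pool are not divided by miRNA in the tables and the design names no second group.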

How the results depend on the processing

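Results with only unique hairpins in the neural and cluster tests, totals without Mir99a, and the choroid plexus or ciliated and sensory lists among the other tissues were alternatives chosen after seeing the data. Of 120 alternative values, 100 kept their direction and side of the threshold, moved by less than the spread or, for counts of genes, stayed within 1.5 times the count reported, 19 moved further, 1 lost its call, and none reversed. Among the 100 are the shares of all 21 lists without replicate 1 and of all 21 without replicate 2. With 2 libraries, leaving 1 out always moves a mean share by less than the SD. These list shares could therefore not have moved further, and leaving out a library did not test them. A minimum of 1 count gave 634 detected genes. Leaving out Mir99a gave 47.7% for the 10 most abundant genes. Pearson's r was 0.991 with a pseudocount of 0.1, 0.997 with 10 and 0.997 with no filter. The genes that differed between the libraries numbered 178 with no minimum fold and 17, including all 7 called above, when only genes at 10 counts in either library were tested, where the adjustment covers fewer genes. With unique hairpins alone, the share of counts was 1.18% for neuron-associated, 0.310% for neural progenitor, 12.7% for let-7, 2.17% for miR-181, 2.90% for Dlk1-Dio3, 0% for Sfmbt2, 0.0135% for pluripotency and 0.0358% for pancreas and gut miRNAs. Counts on either strand gave 13.0% for let-7, 3.34% for miR-181 and 2.19% for endothelial miRNAs, since the added counts enlarge the total, and 0.0322% for immune miRNAs, since they include Mir142b. The added counts also include those at the positions of Mirlet7e and Mirlet7f-1. These carry other gene IDs and so entered the total but not the let-7 share. The neural difference passed its test in all 9 alternatives, with values from 3.03 to 6.57, and was 3.95 with the choroid plexus or ciliated and sensory lists added. The cluster difference (permuted minus observed standard deviation) ranged from 0.340 to 0.392 with 1 library left out and lost its call without replicate 1. The cause was not tested. The difference was 0.454 as reported, 0.392 at a gap of 3 kb, 0.607 at 50 kb, 0.479 with counts on either strand, 0.505 with unique hairpins alone (p = 0.0245) and 1.70 with no filter on low counts, and passed the permutation test in these 5 alternatives. The value with no filter includes neighbouring genes at or near 0 counts, which are similar by default. No paired analysis was possible because there is 1 group. Another 46 genes reached 10 counts in only 1 library, and whether depth limits the rare genes was not tested.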

Other observations

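The tests of the miR-200 family were chosen after its values were seen, as was the grouping of the neuron-associated and let-7 lists. Genes named below outside the rule for named genes were chosen after their values were seen.

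The 5 genes of the miR-200 family moved together between the libraries although they lie on different chromosomes. Mir200a, Mir200b and Mir429 on chromosome 4 were 1.99-fold, 1.69-fold and 2.23-fold higher in replicate 2, and Mir200c and Mir141 on chromosome 6 were 1.88-fold and 1.98-fold higher. Mir183 of the sensory cluster was 1.69-fold higher in replicate 2, and its cluster neighbours Mir182 and Mir96 were 1.22-fold and 1.11-fold higher, the last with a Fisher's exact adjusted p of 1. The erythroid Mir144 was 4.97-fold higher in replicate 2, while Mir451a, which lies next to it on chromosome 11, was 1.31-fold higher.

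Summed over its 5 genes, the miR-200 family was 2.05-fold higher in replicate 2 (95% Wilson counting interval 1.96 to 2.15), which excludes error in counting independent reads. The interval does not cover PCR copies, which are not independent molecules. Mir205, which some epithelia express along with this family, had a ratio of 0.862 (0.714 to 1.04), and Mir203 one of 1.12 (1.09 to 1.16), which as single genes neither show nor exclude such a tissue. The sensory list was higher in replicate 2 in 3 of 3 genes (median log2 ratio 0.29, adjusted p = 0.138 against random lists), while the choroid plexus and ciliated cell list was higher in replicate 1 in 7 of 7 genes (-0.27, adjusted p = 0.379; 5 of 7 with TMM). Another tissue carried along in dissection may account for the difference, and this stays open. The collection day differs with the library, so it cannot be told apart from any other difference between the libraries.

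As let-7 rises and the miR-17~92 family falls during neural differentiation, a difference in developmental progress between the samples was a hypothesis for their opposite shifts. The neuron-associated and let-7 lists together had a median log2 ratio of 0.02, with 14 of 27 genes higher in replicate 2. This was 0.38 above the median of -0.36 of the miR-17~92 family (bootstrap 95% interval 0.21 to 0.65), so most of the difference came from that family. The difference excludes error in counting independent reads (Poisson draws from -0.02 to 0.02) and a trend with abundance as the whole cause (0.46 after its removal). The linear trend with hairpin GC content was nearly flat, and its removal left the difference at 0.38 (bootstrap 95% interval 0.21 to 0.65). This argues against such a trend as the whole cause, and other effects of GC content were not tested. Chance in the choice of genes stays open, since the percentile of 99.96 among matched random lists belongs to a grouping chosen after counts had been seen. The neuron-associated list alone decided nothing, with a median of -0.13 and 6 of 17 genes higher in replicate 2 (-0.05 and 8 of 17 with TMM, -0.02 and 8 of 17 with median-of-ratios factors, -0.06 and 8 of 17 without Mir99a). Developmental progress may contribute, but the labels give both samples the same age, and collection day and library preparation stay open.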
